A study of Homo sapiens with 12 samples.

How the data were processed

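The series holds RNA-seq of MDA-231-LM2, a line derived from the human breast cancer line MDA-MB-231 by selection for lung metastasis. The labels give a 2 by 2 design of 4 groups with 3 libraries each, 12 libraries in all. The first factor is the cell population, labelled Ctrl or TMEM216, and the other is IGF1, absent or added. The labels do not say what was done to TMEM216, nor the dose or duration of IGF1. They do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels, total RNA was made into libraries with an Illumina TruSeq RNA kit; whether the libraries kept strand is not given in the sources used here.

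The authors deposited TPM, a transcript abundance scaled to a fixed total per library, for 21574 features, and per the submitters' processing notes HISAT2, StringTie and RSEM were used, without versions. The genome build and annotation are not given in the sources used here either, so no coordinates are printed. Of the features, 20443 carried Ensembl gene identifiers, and every one matched a gene name; the other 1131 were assembled features with MSTRG names. TPM holds no read counts, so the depth of each library is unknown and no counting interval is given. A TPM listed as 0 can be a failed estimate and is described only as listed at 0.

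From the TPM values, log2(TPM + 1) was computed without further scaling, and features with a TPM of at least 1 in 3 or more libraries were kept. This left 13071 features, 519 of them MSTRG features. Fold changes on this scale understate the change of low genes. The 4 groups were fitted together with limma (version 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package), with moderated variances and a mean-variance trend. The contrasts tested, all two-sided, were IGF1 within each cell population, TMEM216 within each IGF1 condition, and the interaction. Adjusted p is the Benjamini-Hochberg value from limma over the 13071 features, and the threshold was 0.05. SE is limma's moderated standard error. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

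Before the data were examined, 42 gene lists were written for ciliary, IGF, growth factor, metabolic, stress, cell cycle, inflammatory, adhesion and metastasis genes and for markers of other cell types. Of these, 39 had at least 5 tested members. Some genes belong to more than 1 list. Each list was compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 39 lists within a contrast. Camera was given the same mean-variance trend as the limma fit. That detail was set after list calls without it had been seen, and those calls are given among the alternatives. Counts of members past the threshold are over all features unless described as adjusted over the list alone. Camera with a correlation estimated per list, and fry, a directional test that does not compare a list with other genes, were alternatives.

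The named genes follow a rule fixed beforehand. It takes up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, with a mean TPM of at least 5, no overlap between the libraries of the 2 groups (not asked of the interaction) and a proper symbol. Chance alone separates 3 libraries from 3 without overlap in 10% of genes. TMEM216, IGF1R, IRS1 and IRS2 are always included, as are up to 4 members with the smallest p of each list described. The rule gives the 5 smallest p where no gene qualifies in either direction; after the data were seen this was applied to each direction separately, and such genes are said not to pass. Genes outside the rule are described as chosen after their values were seen.

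Overlap between genes was looked up in GENCODE v29, used only for names, order and overlap of genes. Of 47 leading named genes, 8 overlapped another tested gene. SRSF1 and ST6GALNAC6 did so on the same strand, and ADIRF, FOSB, IL6, LYPD1, PCK2 and PLLP on the opposite strand. Genes named only as list members are not in this count. Some of them also overlap a tested gene, such as KRT8, COL18A1, HSP90B1 and CA9, on the opposite strand. Reads of these genes could be split with the overlapping gene, and their values are uncertain to that extent. Transcript length and GC content were those of the longest GENCODE v29 transcript, found for 12482 of the tested features (95.5%). All members of each tested list had a length, except in the histone list (87.5%) and the FOXO and NF-kB lists (96.7% each). List medians after correction cover only members with a length, while those before it cover all members.

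The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum TPM of 5, quantile normalization, median-of-ratios scaling, no mean-variance trend, a fit of only the 6 libraries compared, the replicate number as a block, leaving out each library in turn (with the features of the full fit), and a minimum absolute log2 fold change of 1. Alternatives chosen after seeing the data were removal of Ctrl+IGF1 replicate 3 and TMEM216 replicate 1, contrasts averaged over the other factor, a loess correction of fold changes on transcript length and GC content (span 0.5), camera without the trend, and the p53 list without the genes it shares with the ATF4 list. The 2 libraries removed together had the lowest scores on the first principal component; the 2 at its other end were not removed together. The fit was tested on simulated data with 200 changed genes among the 13071. For the TMEM216 contrast without IGF1 it recovered 47.8% of genes changed by 0.5 on the log2 scale, 92.5% at 1 and 100% at 2, with 11 of 12871 unchanged genes called. For the interaction these shares were 16.4%, 62.7% and 87.9%, with 7 unchanged genes called. The simulated noise was drawn independently for each gene and library, without differences that many genes of a library share. The rates may therefore not hold for the real libraries.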

Results

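The data comprise 12 transcriptomes of MDA-231-LM2 breast cancer cells in the groups Ctrl, Ctrl+IGF1, TMEM216 and TMEM216+IGF1, with 3 libraries each. By its title, the series asks what TMEM216 does to the transcriptome of these cells. TMEM216 encodes a membrane protein of the ciliary transition zone, and IGF1 is a ligand of the receptor IGF1R. Expression is given as TPM, so sequencing depth is unknown. Correlations between libraries on the log2 scale ranged from 0.977 to 0.990, and no pair was identical. On the first principal component, which held 22% of the variance, Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 had the lowest scores (-31.0 and -19.4). TMEM216 replicate 3 and TMEM216+IGF1 replicate 2 lay at its other end (18.2 and 18.1), about as far out as TMEM216 replicate 1, and were left out only one at a time. Ribosomal protein genes took 16.9% of all TPM in Ctrl+IGF1 replicate 3, against 12.4% to 14.6% in the other libraries.

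TMEM216 transcript was higher in every library labelled TMEM216 than in every library labelled Ctrl. Its level was 219 ± 29.2 TPM (SD, n = 6) in the TMEM216 libraries and 26.8 ± 2.68 TPM (SD, n = 6) in the Ctrl libraries, an 8.15-fold difference. The ranges, 163 to 250 TPM and 24.0 to 30.1 TPM, did not overlap (two-sided exact permutation test, p = 0.00216, the smallest that 924 splits can give). The log2 fold change was 2.94 (SE 0.14, adjusted p = 9.35e-07) without IGF1 and 3.01 (SE 0.14, adjusted p = 3.63e-07) with IGF1. IGF1 itself left TMEM216 within the spread of the libraries, with log2 changes of 0.049 (SE 0.14) in Ctrl and 0.11 (SE 0.14) in TMEM216 cells.

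**Figure D1:**
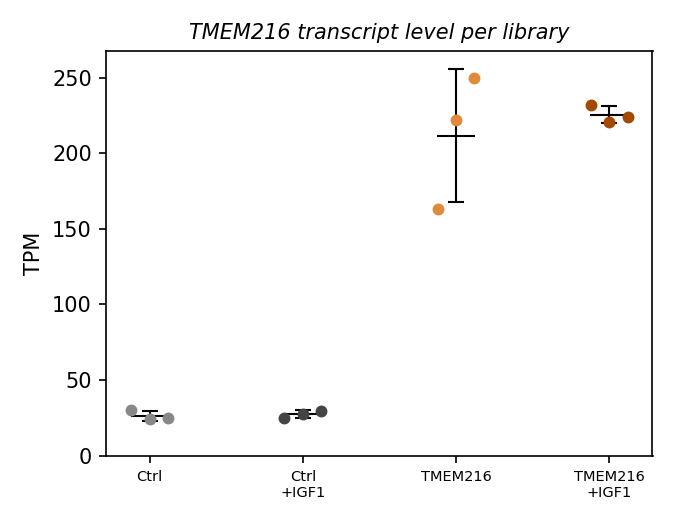
TMEM216 level in TPM (vertical axis) in each of the 4 groups (horizontal axis); points are libraries, and bars show the mean and SD of 3 libraries. The 6 TMEM216 libraries lie between 163 and 250 TPM, all above the 6 Ctrl libraries at 24.0 to 30.1 TPM.

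The first comparison asked how TMEM216 cells differed from Ctrl cells without IGF1. PCK2, a mitochondrial phosphoenolpyruvate carboxykinase, fell from 46.8 ± 1.85 to 20.4 ± 0.963 TPM (SD, n = 3 here and for each level below), a log2 change of -1.16 (SE 0.075, adjusted p = 1.2e-05). IL6, an inflammatory cytokine, fell from 195 ± 4.30 to 92.9 ± 3.23 TPM (log2 -1.06, SE 0.061, adjusted p = 4.85e-06). EDN1, the precursor of endothelin 1, fell from 60.5 ± 0.543 to 29.3 ± 2.69 TPM (log2 -1.02, SE 0.077, adjusted p = 5.03e-05). IL6 and PCK2 each overlap another gene on the opposite strand. Of 13071 features, 143 passed the threshold, 20 higher and 123 lower in TMEM216 cells.

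Besides TMEM216, the largest rises were modest. NQO1, a quinone reductase, rose from 228 ± 3.67 to 352 ± 7.62 TPM (log2 0.62, SE 0.062, adjusted p = 3.52e-04). COL6A1, a collagen VI chain, rose from 166 ± 6.04 to 245 ± 11.7 TPM, and HLA-DRA, an MHC class II chain, from 24.6 ± 1.13 to 40.4 ± 2.80 TPM. SCD, a fatty acid desaturase, rose from 27.6 ± 1.34 to 45.1 ± 6.39 TPM, and ADIRF from 76.3 ± 3.32 to 139 ± 9.85 TPM. SLCO3A1, COMMD10, GGH and LYPD1 rose by log2 0.73, 0.58, 0.51 and 0.50. The largest falls also included the AP-1 repressor JDP2 (21.5 ± 4.51 to 3.70 ± 0.551 TPM), the matrix metalloprotease MMP3 (20.9 ± 0.954 to 9.24 ± 1.36 TPM), the stress protein NUPR1 (16.3 ± 2.19 to 7.26 ± 1.28 TPM) and the early response factor EGR1 (43.4 ± 2.18 to 18.8 ± 3.20 TPM). The call of ADIRF was lost on leaving out any Ctrl library or TMEM216 replicate 1 or 2 (log2 0.79 where nearest 0), that of SCD in each leave-one-out fit except those without Ctrl+IGF1 replicates 2 and 3 and TMEM216 replicate 1 (log2 0.58 where nearest 0) and that of COMMD10 on leaving out Ctrl replicate 1 or 2 (log2 0.53 where nearest 0). GGH lost its call in each leave-one-out fit except those without Ctrl+IGF1 replicate 3 and TMEM216 replicate 3 (log2 0.41 where nearest 0), LYPD1 in each leave-one-out fit except those without Ctrl+IGF1 replicates 2 and 3, TMEM216 replicate 3 and TMEM216+IGF1 replicates 2 and 3 (log2 0.45 where nearest 0) and NUPR1 in each leave-one-out fit except those without Ctrl+IGF1 replicate 3 and TMEM216+IGF1 replicates 1 and 2 (log2 -0.94 where nearest 0). IGF1R, IRS1 and IRS2 did not pass, with log2 changes of -0.046 (SE 0.13), -0.23 (SE 0.13) and -0.13 (SE 0.13).

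The list of ATF4 amino acid response genes, which serve amino acid synthesis, uptake and tRNA charging, was lower in TMEM216 cells without IGF1. Of 32 measured members, 18 fell and none rose (29 fell adjusted over the list alone), with a median log2 change of -0.60 (camera, adjusted p = 6.13e-35). Its call held with an estimated correlation (adjusted p = 0.010), the only one of the 18 list calls in this contrast to do so. Among its members, ASNS, asparagine synthetase, fell (log2 -0.94, SE 0.075), as did TRIB3, a pseudokinase (log2 -1.11, SE 0.092), CHAC1, which degrades glutathione (log2 -1.65, SE 0.15), and CTH, the cystathionine gamma-lyase (log2 -1.33, SE 0.13). ATF4 transcript was at 742 TPM in Ctrl and 605 TPM in TMEM216 cells (log2 -0.29, adjusted p = 0.118), which did not pass.

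Inflammatory and early response lists were also lower, though their calls were lost with an estimated correlation. In the NF-kB and cytokine list, 6 of 30 members fell and none rose (11 fell and 1 rose adjusted over the list alone), among them IL6 and the cytokines CXCL1 and IL1A at log2 -0.55 and -0.71 (adjusted p = 0.0596 with an estimated correlation). In the immediate early and ERK feedback list, FOSB, EGR1, DUSP1 and FOS fell of 34 members (10 fell adjusted over the list alone), with log2 changes of -1.90, -1.18, -0.81 and -0.68 (adjusted p = 0.375 with an estimated correlation). The call of FOS was lost on leaving out any Ctrl library or TMEM216 replicate 2 (log2 -0.63 where nearest 0) and with only the 6 libraries compared. Epithelial genes were lower, with KRT8 (log2 -0.38), KRT19 (-0.38), CD24 (-0.57) and CLDN1 (-0.68) falling of 21 members (5 fell adjusted over the list alone; adjusted p = 0.273 with an estimated correlation). Of 27 p53 targets, SESN2, BBC3 and GDF15 fell (6 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). SESN2 and GDF15 also belong to the ATF4 list, so their falls are counted in both; without them the p53 list had a median of -0.12 (adjusted p = 0.0203). KRT8 lost its call on leaving out any Ctrl library or TMEM216 replicate 2 (log2 -0.37 where nearest 0), KRT19 in each leave-one-out fit except those without Ctrl+IGF1 replicates 2 and 3 and TMEM216 replicate 1 (log2 -0.29 where nearest 0), CD24 on leaving out Ctrl replicate 2 or 3 or TMEM216 replicate 1 or 2 (log2 -0.51 where nearest 0), CLDN1 in each leave-one-out fit except those without Ctrl+IGF1 replicates 2 and 3 (log2 -0.55 where nearest 0), BBC3 on leaving out Ctrl replicate 1 or 3 or TMEM216 replicate 2 or 3 (log2 -0.73 where nearest 0) and GDF15 in each leave-one-out fit except those without Ctrl+IGF1 replicates 1, 2 and 3 and TMEM216+IGF1 replicate 2 (log2 -0.58 where nearest 0).

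NRF2 targets, which serve redox metabolism, were higher as a list in TMEM216 cells without IGF1, at a median of 0.21. NQO1 and AKR1C3 (log2 0.42) rose of 23 members (7 rose and 2 fell adjusted over the list alone; adjusted p = 0.0596 with an estimated correlation). HMOX1, a further NRF2 target, stood at log2 -0.42 and did not pass. The collagen and matrix list was higher, with COL6A1 and COL6A3 (log2 0.56) rising and COL1A1 falling (log2 -0.46) of 33 members (3 rose and 2 fell adjusted over the list alone; adjusted p = 0.643 with an estimated correlation). The call of AKR1C3 was lost in each leave-one-out fit except those without Ctrl+IGF1 replicates 1, 2 and 3 and TMEM216+IGF1 replicates 2 and 3 (log2 0.40 where nearest 0), of COL1A1 on leaving out any Ctrl library (log2 -0.45 where nearest 0) and of COL6A3 in each leave-one-out fit except those without Ctrl+IGF1 replicate 3 (log2 0.48 where nearest 0).

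The other lists past the threshold without IGF1 had medians between -0.19 and 0.092, and the median over all features was -0.048. FOXO targets, YAP and TEAD targets and the lysosome list were lower, at medians of -0.19, -0.12 and -0.15 (adjusted p = 0.572, 0.675 and 0.643 with an estimated correlation). The G2/M, cholesterol, fatty acid and lung metastasis lists were higher, at medians of 0.033, 0.012, 0.074 and 0.092 (adjusted p = 0.753, 0.643, 0.643 and 0.643 with an estimated correlation). So were the ribosomal protein, oxidative phosphorylation, histone and ribosome biogenesis lists, at medians of 0.056, 0.052, 0.060 and 0.055 (adjusted p = 0.675, 0.643, 0.273 and 0.643 with an estimated correlation), and these calls were lost without TMEM216 replicate 1 and after quantile normalization. After correction for length and GC content the medians of these 4 lists were 0.034, -0.0016, 0.00051 and 0.032, and that of the G2/M list was -0.012, while those of the cholesterol, collagen and lung metastasis lists rose to 0.023, 0.090 and 0.15. Single libraries also ended the calls for the G2/M, cholesterol and fatty acid lists (TMEM216 replicate 3), the YAP and TEAD list (Ctrl replicate 3 or TMEM216 replicate 1), the histone list (also Ctrl replicate 3, TMEM216 replicate 3 and TMEM216+IGF1 replicates 1 and 2) and the lung metastasis list (Ctrl replicate 2 and TMEM216 replicates 2 and 3). Processing settings ended the calls for the lung metastasis list (no filter, a minimum TPM of 5, quantile normalization and median-of-ratios scaling), the histone list (a pseudocount of 0.1, a minimum TPM of 5 and median-of-ratios scaling), the G2/M list (quantile normalization) and the collagen and fatty acid lists (no filter). The ribosomal, oxidative phosphorylation, histone and YAP and TEAD calls were lost without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 together. Ciliary lists did not pass: the transition zone list had a median of -0.017 over 21 genes (adjusted p = 0.685), the intraflagellar transport list -0.086 over 42 (adjusted p = 0.869) and the Hedgehog list -0.040 over 10 (adjusted p = 0.748).

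The count of 143 depended on the libraries and on the fit. It was 43, 48, 50 and 54 without Ctrl replicates 2, 1 and 3 and TMEM216 replicate 2, 90 and 92 without TMEM216+IGF1 replicate 1 and Ctrl+IGF1 replicate 1, 273 without Ctrl+IGF1 replicate 3, and 49 from the 6 libraries compared alone. The share of higher genes, 14%, was 32.8% (60 of 183) after quantile normalization and 29.1% (55 of 189) after median-of-ratios scaling.

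The TMEM216 effect with IGF1 was compared in the 6 libraries that received it. FOS, a subunit of the transcription factor AP-1, fell from 65.5 ± 4.47 to 11.0 ± 0.888 TPM (log2 -2.47, SE 0.11, adjusted p = 3.63e-07). SCD rose from 28.1 ± 5.74 to 65.8 ± 3.41 TPM (log2 1.22, SE 0.14, adjusted p = 8.28e-04). CHAC1 fell from 27.8 ± 2.48 to 6.06 ± 1.01 TPM (log2 -2.03, SE 0.15, adjusted p = 2.46e-05). In all, 211 features passed, 120 higher and 91 lower in TMEM216 cells.

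Further rises with IGF1 included TIMP3, an inhibitor of matrix metalloproteases (85.4 ± 15.5 to 157 ± 9.44 TPM), the integrin chain ITGA2 (46.3 ± 10.9 to 83.3 ± 10.5 TPM), the carbonic anhydrase CA12 (10.5 ± 2.09 to 19.8 ± 0.620 TPM) and the ephrin EFNB2 (18.4 ± 2.65 to 33.0 ± 1.70 TPM). ST6GALNAC6, GPRC5C, DHRS3 and PLLP rose by log2 1.05, 0.98, 0.90 and 0.87. Further falls included NUPR1, EGR1 (29.8 ± 2.07 to 9.98 ± 1.34 TPM), EDN1 (45.6 ± 1.53 to 20.1 ± 0.213 TPM), CTH, MMP3 and TRIB3, at log2 -1.58, -1.49, -1.14, -1.28, -1.04 and -1.04. C6orf132 and the hair keratin-associated KRTAP2-3 fell, with log2 changes of -1.46 and -1.18. ST6GALNAC6 lost its call on leaving out Ctrl+IGF1 replicate 1 or TMEM216+IGF1 replicate 1 or 2 (log2 0.97 where nearest 0), PLLP on leaving out TMEM216+IGF1 replicate 1 (log2 0.84 where nearest 0) and ITGA2 in each leave-one-out fit except those without Ctrl+IGF1 replicate 2 and TMEM216 replicates 1 and 3 (log2 0.66 where nearest 0). IGF1R, IRS1 and IRS2 stood at log2 0.29 (SE 0.13), 0.041 (SE 0.13) and -0.083 (SE 0.13) and did not pass.

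Of the ATF4 list, 14 of 32 members fell with IGF1 (21 adjusted over the list alone), with a median of -0.36 (adjusted p = 2.72e-31, and adjusted p = 0.0145 with an estimated correlation). The call held in all 20 other alternatives run for it, as it did without IGF1. It was again the only one of 18 list calls held with an estimated correlation. Across both IGF1 conditions 13 members fell in each, and 30 of 32 had lower fitted values in each. NRF2 targets had a median of 0.22, with NQO1 (log2 0.64) and AKR1C3 (0.74) among those rising (8 of 23 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation). Collagen and matrix genes were higher, with COL6A1, COL6A3 and COL18A1 rising by log2 0.76, 0.83 and 0.53 (16 rose and 2 fell of 33 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). Cholesterol genes had a median of 0.26, with INSIG1 and IDI1 rising by log2 0.46 and 0.35 (5 of 25 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). Fatty acid synthesis genes had a median of 0.29, where SCD rose (7 of 18 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). COL18A1 lost its call on leaving out TMEM216+IGF1 replicate 1 or 3 (log2 0.47 where nearest 0). INSIG1 and IDI1 lost theirs in each leave-one-out fit except those without Ctrl+IGF1 replicate 2 and TMEM216 replicates 1 and 3 (log2 0.40 and 0.31 where nearest 0).

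In the lung metastasis list, written from genes linked to lung colonisation by this line, IL13RA2 and ID1 rose (log2 0.56 and 0.45) and CXCL1, also in the NF-kB list, fell (-0.46) of 16 members (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). ID1 lost its call in each leave-one-out fit except those without Ctrl+IGF1 replicate 3 and TMEM216 replicates 1 and 3 (log2 0.39 where nearest 0). In the endoplasmic reticulum stress list, the chaperones HSP90B1 and CALR rose (log2 0.55 and 0.33) while HERPUD1 and XBP1 fell (-0.60 and -0.41) of 25 members (7 rose and 2 fell adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). HERPUD1 lost its call on leaving out Ctrl+IGF1 replicate 1 or 3 or any TMEM216+IGF1 library (log2 -0.52 where nearest 0), CALR in each leave-one-out fit except those without Ctrl+IGF1 replicate 2 and TMEM216 replicates 1 and 3 (log2 0.27 where nearest 0) and XBP1 in each leave-one-out fit except those without Ctrl+IGF1 replicate 3 and TMEM216 replicates 1 and 3 (log2 -0.35 where nearest 0).

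Further lists were higher with IGF1, namely G2/M, IGF signalling, glycolysis and integrin genes, at medians of 0.15, 0.16, 0.17 and 0.18 (adjusted p = 0.665, 0.489, 0.599 and 0.679 with an estimated correlation). The NF-kB, immediate early and p53 lists were lower, at medians of -0.077, -0.023 and -0.050, as were epithelial genes by their test, although their median of 0.011 was positive, and negative under both other scalings (adjusted p = 0.489 for each of the 4 with an estimated correlation). The median over all features was 0.048 in this contrast. After correction for length and GC content the medians of the NF-kB, immediate early, p53 and epithelial lists were -0.016, 0.0037, 0.0028 and 0.0051. The NF-kB call was lost with no filter, with quantile normalization and without Ctrl+IGF1 replicate 3, alone or together with TMEM216 replicate 1. The integrin call was lost without Ctrl+IGF1 replicate 3 and the epithelial call without TMEM216+IGF1 replicate 3. The transition zone, ciliary trafficking and Hedgehog lists did not pass here either, at medians of 0.064, 0.074 and 0.14. The ribosomal protein list had a median of -0.16, with no member past the threshold among 78, over all features or adjusted over the list alone (adjusted p = 0.513 with an estimated correlation). Oxidative phosphorylation genes and histones had medians of -0.13 and -0.079 (adjusted p = 0.513 and 0.266 with an estimated correlation), and these 3 calls were lost without Ctrl+IGF1 replicate 3, alone or together with TMEM216 replicate 1. The histone call was also lost with no filter, a minimum TPM of 5, quantile normalization or median-of-ratios scaling. After the same correction the ribosomal, oxidative phosphorylation and histone medians were -0.086, -0.012 and 0.10. That of the histones, taken over members with a length, thus turned in sign. Those of the 10 lists higher in TMEM216 cells lay between 0.15 and 0.34. The TMEM216 effect with IGF1 also followed transcript length: over 12331 genes outside the ribosomal and respiratory chain lists its rank correlation with length was 0.34, across genes, which are not independent replicates. Rank correlations with GC content were -0.32 there and -0.23 for the TMEM216 effect without IGF1, whose rank correlation with length was 0.020. The count of 211 was 84, 88 and 117 without TMEM216+IGF1 replicates 1, 2 and 3, 91 and 139 without Ctrl+IGF1 replicate 1 and Ctrl replicate 3, 462 without Ctrl+IGF1 replicate 2, and 49 from the 6 libraries alone.

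The TMEM216 effects without and with IGF1 share no libraries. Of the genes past the threshold, 13 rose and 48 fell in both, where independent lists would share 0.184 and 0.856, and none went opposite ways. Both effects come from the same fit, with a shared estimate of each gene's spread. Calls of the same gene are therefore not independent, and the expected counts are only a rough guide. Across 13071 features, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.335 and Spearman's rho of 0.368. Over the 12482 features with a transcript length these were 0.421 and 0.391, and 0.418 and 0.399 after correction for length and GC content. The corresponding r for the IGF1 effects in Ctrl and TMEM216 cells was 0.013 (rho -0.0084). The averaged IGF1 and TMEM216 effects had an r of 0.051 (rho -0.0024).

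**Figure D2:**
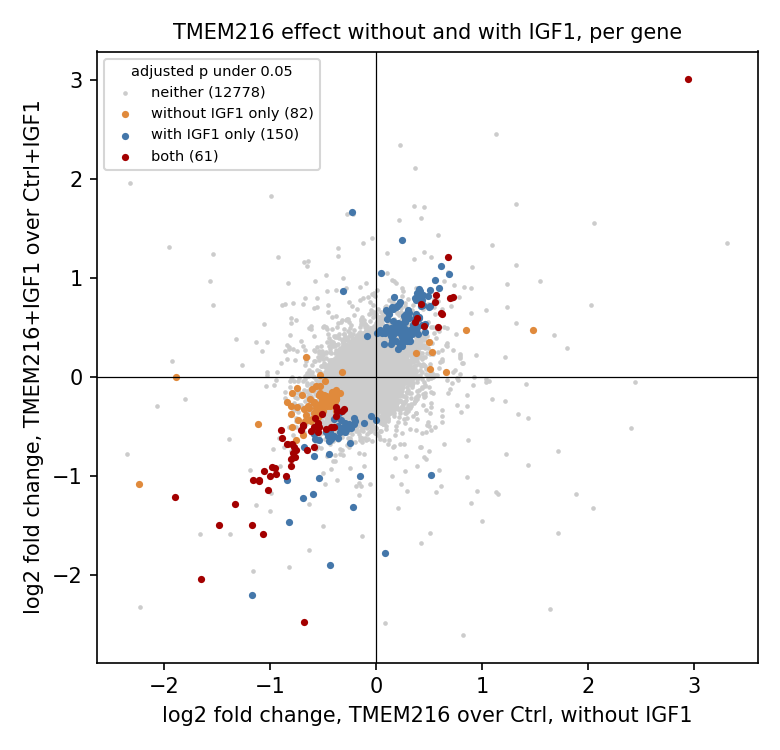
Log2 fold change of TMEM216 over Ctrl for each of 13071 features, without IGF1 (horizontal axis) and with IGF1 (vertical axis), on the log2(TPM + 1) scale. Colours mark features past the threshold in both effects (61), without IGF1 only (82), with IGF1 only (150) or in neither (12778); the point at the upper right is TMEM216.

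**Figure D3:**
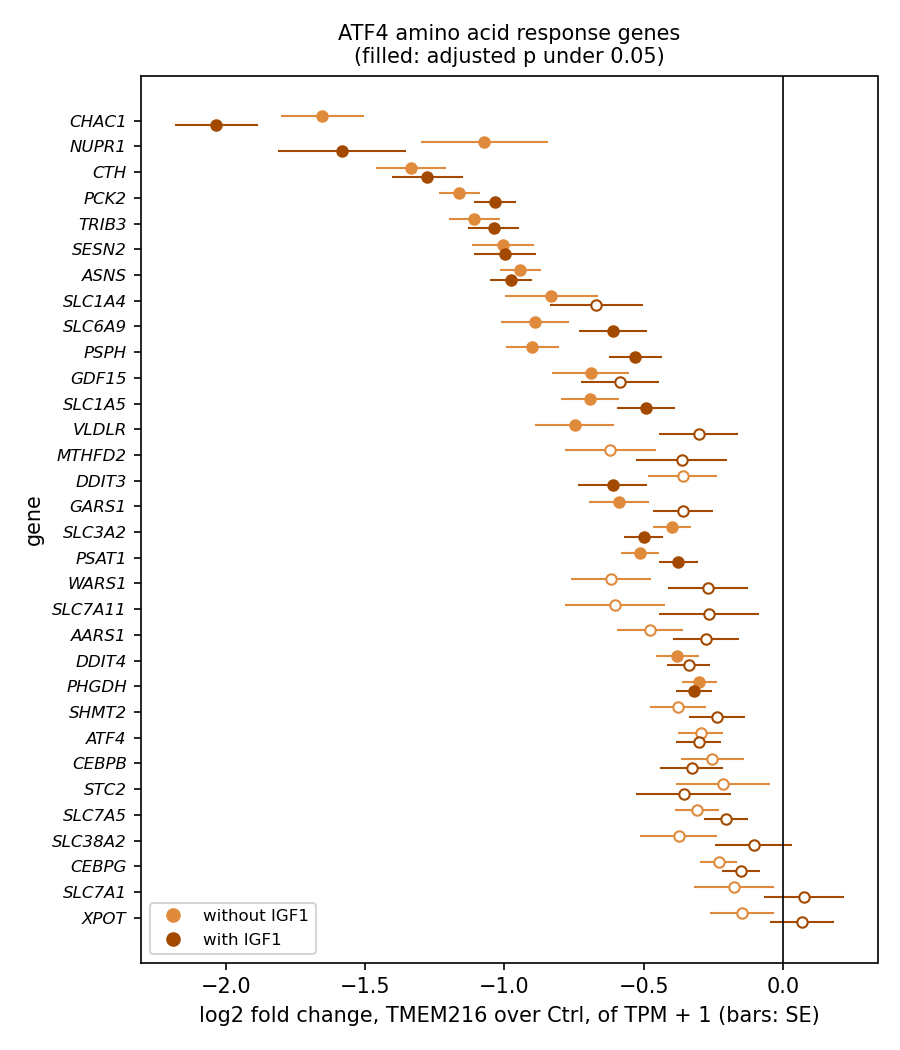
Log2 fold change (horizontal axis, bars show SE) of the 32 measured ATF4 amino acid response genes (vertical axis) in TMEM216 over Ctrl cells, without and with IGF1. Filled points passed the threshold (18 without and 14 with IGF1), and 30 genes lie below 0 in both.

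The IGF1 effect in Ctrl cells was small at the level of single genes. FOSB, an AP-1 subunit, fell from 8.70 ± 1.02 to 3.20 ± 0.831 TPM (log2 -1.22, SE 0.16, adjusted p = 0.0386). The splicing factor SRSF1 fell from 258 ± 5.76 to 137 ± 25.6 TPM (log2 -0.92, SE 0.13, adjusted p = 0.0425), and the membrane protein PLLP from 7.58 ± 0.212 to 3.40 ± 0.919 TPM (log2 -0.98, SE 0.14, adjusted p = 0.0477). ENSG00000266086, which overlaps SRSF1 on the same strand, went from 102 ± 9.97 to 165 ± 17.3 TPM, so the split of reads between the pair, and with it the fall of SRSF1, is uncertain. The other of the 4 features past the threshold, ENSG00000273049, was at 1.90, 2.94 and 3.49 TPM in the Ctrl libraries and listed at 0 in the other 9. FOSB, with a mean TPM under 5, and this feature were named after their values were seen. The call of FOSB was lost in each leave-one-out fit except those without Ctrl+IGF1 replicate 2 and TMEM216 replicate 1 (log2 -1.11 where nearest 0), that of SRSF1 in each leave-one-out fit except those without Ctrl+IGF1 replicate 1 and TMEM216 replicate 1 (log2 -0.80 where nearest 0) and that of PLLP in each leave-one-out fit except those without Ctrl+IGF1 replicate 1 (log2 -0.88 where nearest 0).

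No gene rose past the threshold with IGF1 in Ctrl cells, where 900 features had an unadjusted p under 0.05 in limma, in either direction. The highest ranked, none past it, were S100A2, RPL11, CXCL3, IFI6 and OASL, at log2 0.38, 0.41, 0.42, 0.43 and 0.44. FOS and EGR1 were at 65.5 ± 4.47 and 29.8 ± 2.07 TPM with IGF1, against 103 ± 4.16 and 43.4 ± 2.18 without, and did not pass over all features (adjusted p = 0.158 and 0.564). IGF1R, IRS1 and IRS2 were at log2 -0.41 (SE 0.13), -0.19 (SE 0.13) and -0.19 (SE 0.13) and did not pass. The 4 calls became 0 with a pseudocount of 0.1 or a minimum TPM of 5, and 1 without any single Ctrl or TMEM216+IGF1 library, or without TMEM216 replicate 2 or 3.

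In this contrast 12 lists passed, where the median over all features was -0.088. Ribosomal protein genes were higher with IGF1, at a median of 0.18 over 78 genes, none past the threshold over all features (1 rose adjusted over the list alone; adjusted p = 0.560 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of 0.14 over 73 (none past, also adjusted over the list alone; adjusted p = 0.343 with an estimated correlation). Without Ctrl+IGF1 replicate 3 the medians of the cytoplasmic ribosomal proteins and nuclear oxidative phosphorylation genes were 0.047 and 0.048. Replication-dependent histones had a median of 0.12 over 24 genes, and theirs was the only call held with an estimated correlation (adjusted p = 0.0106). In this contrast the rank correlation of change was -0.36 with transcript length and 0.17 with GC content over 12331 genes. After correction for length and GC content the ribosomal, oxidative phosphorylation and histone medians were 0.071, 0.021 and -0.037, the last over members with a length.

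Lists lower with IGF1 in Ctrl cells included YAP and TEAD targets, at a median of -0.25 (6 of 27 fell adjusted over the list alone, none over all features; adjusted p = 0.560 with an estimated correlation). CCN2, a matricellular growth regulator, stood at log2 -0.47 there. IGF signalling components had a median of -0.15 (5 of 18 fell adjusted over the list alone; adjusted p = 0.560 with an estimated correlation), with IGFBP3, IGFBP1 and INSR at log2 -0.33, -0.46 and -0.38. FOXO targets had a median of -0.16 (none past in either count, that adjusted over the list alone included; adjusted p = 0.703 with an estimated correlation). In the immediate early list FOSB fell over all features, and 4 of 34 members fell adjusted over the list alone (adjusted p = 0.703 with an estimated correlation). The G1/S, G2/M and Wnt lists were lower, at medians of -0.14, -0.17 and -0.19, against -0.088 over all features (adjusted p = 0.703 for each with an estimated correlation). The ribosome biogenesis and NF-kB lists were higher by their tests, although their medians of -0.0032 and -0.056 were negative, and positive under both other scalings (adjusted p = 0.560 for each with an estimated correlation). Both medians lay above that over all features, with which the test compares a list. After correction for length and GC content the ribosome biogenesis and NF-kB medians were lower, at -0.030 and -0.071. Without Ctrl+IGF1 replicate 2 the calls for IGF signalling, FOXO, immediate early, Wnt, ribosome biogenesis and NF-kB lists were lost. The immediate early call was also lost with a pseudocount of 0.1 or median-of-ratios scaling, the Wnt and NF-kB calls with quantile normalization, and the Wnt call without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 together. Other single libraries ended the calls for FOXO targets (Ctrl replicate 3 and Ctrl+IGF1 replicate 1), the Wnt list (Ctrl replicates 1 and 2 and Ctrl+IGF1 replicate 3), the NF-kB list (Ctrl replicate 2 and Ctrl+IGF1 replicate 1) and the immediate early list (Ctrl replicates 2 and 3, Ctrl+IGF1 replicate 1, TMEM216 replicate 2 and TMEM216+IGF1 replicates 1 and 3).

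In TMEM216 cells, IGF1 went with a fall of FOS from 64.3 ± 10.6 to 11.0 ± 0.888 TPM (log2 -2.43, SE 0.11, adjusted p = 5.24e-07), and the ranges of the 3 libraries did not overlap. The other of the 2 features past the threshold was the assembled MSTRG.13414.13, which fell (log2 -1.20) and was named after its values were seen. An unadjusted p under 0.05 in limma was reached by 624 features, in either direction, fewer than chance alone would give at that cutoff. No gene rose past the threshold. The highest ranked, none past it, were the colony-stimulating factor CSF3 (1066 ± 34.1 to 1415 ± 69.2 TPM, adjusted p = 0.0587), PTGES, CALB2, IL6 (92.9 ± 3.23 to 114 ± 2.05 TPM) and PTGS2. IGF1R, IRS1 and IRS2 were at log2 -0.074 (SE 0.13), 0.085 (SE 0.13) and -0.14 (SE 0.13) and did not pass. The 2 calls became 1 without Ctrl replicate 3, Ctrl+IGF1 replicate 1 or 2, TMEM216 replicate 1 or any TMEM216+IGF1 library, where FOS remained, and 6 without Ctrl+IGF1 replicate 3, 4 without TMEM216 replicate 3 and 7 with a pseudocount of 0.1.

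The NF-kB and cytokine list was higher with IGF1 in TMEM216 cells, at a median of 0.18, with no member past the threshold over all features and 9 of 30 rising adjusted over the list alone. Its call was the only one of 14 held with an estimated correlation (adjusted p = 0.0371). CXCL8 and PTGS2, a chemokine and the inducible cyclooxygenase, were at log2 0.25 and 0.52 there. Interferon response genes had a median of 0.21 (1 of 41 rose adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). MHC genes had a median of 0.15 (2 of 18 rose adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). Hypoxia response genes had a median of 0.11, with CA9 at log2 0.91 and ADM at -0.41 (3 of 29 rose and 1 fell adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). Endoplasmic reticulum stress, fatty acid, glycolysis, lung metastasis, integrin, lysosome, matrix protease and fibroblast lists were also higher, at medians of 0.16, 0.089, 0.10, 0.17, 0.080, 0.11, 0.10 and 0.15 (adjusted p = 0.409, 0.682, 0.700, 0.409, 0.723, 0.723, 0.723 and 0.409 with an estimated correlation). YAP and TEAD targets and ribosomal proteins were lower, at medians of -0.078 and -0.066 (adjusted p = 0.483 and 0.723 with an estimated correlation). The glycolysis, integrin, lysosome, matrix protease and ribosomal calls were lost without TMEM216 replicate 1, the MHC and fibroblast calls without TMEM216 replicate 3, and the lysosome and fibroblast calls without TMEM216+IGF1 replicate 2. The integrin, lysosome, matrix protease and ribosomal calls were lost without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 together.

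The interaction asked whether IGF1 acted differently in TMEM216 and Ctrl cells. FOS passed, with an interaction of -1.79 on the log2 scale (SE 0.15, adjusted p = 9.65e-04). FOS was at 103 ± 4.16 TPM in Ctrl, 65.5 ± 4.47 in Ctrl+IGF1, 64.3 ± 10.6 in TMEM216 and 11.0 ± 0.888 in TMEM216+IGF1. With any single library left out, its interaction ranged from -1.87 to -1.66. The other of 2 features past the threshold was ENSG00000273049, which was listed at 0 outside the Ctrl libraries. The genes next in rank on the positive side, PLLP, SRSF1, KDM3A, CSF3 and SEMA6B, did not pass (smallest adjusted p = 0.217). EGR1 and FOSB had interactions of -0.31 (SE 0.18) and 0.69 (SE 0.23) and did not pass. IGF1R, IRS1 and IRS2 had interactions of 0.34 (SE 0.19), 0.27 (SE 0.19) and 0.049 (SE 0.18) and did not pass. Of the features tested, 703 had an unadjusted p under 0.05 in limma, close to the number that chance alone would give. FOS alone passed without Ctrl replicate 3, Ctrl+IGF1 replicate 2 or 3, TMEM216 replicate 1 or any TMEM216+IGF1 library, a count of 1.

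For 14 lists the interaction also passed, 10 of them higher and 4 lower than the other genes. The median interaction over all features was 0.107. Integrin genes had a median interaction of 0.23 and ribosomal protein genes one of -0.23 (adjusted p = 0.709 and 0.492 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.17 (adjusted p = 0.492 with an estimated correlation). Only the histone call held, at a median of -0.11 (adjusted p = 0.0260 with an estimated correlation). No member of these 4 lists passed singly, over all features or adjusted over the list alone. The rank correlation of the interaction with transcript length was 0.32 over 12331 genes, and with GC content -0.12. After correction for length and GC content the histone median turned to 0.074, over members with a length. The ribosomal and oxidative phosphorylation medians were then -0.089 and -0.0052. Those of the 10 lists with positive tests lay between 0.17 (collagens, 0.20 before) and 0.27 (NF-kB, 0.17 before). Without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 the ribosomal and oxidative phosphorylation medians were -0.048 and -0.017, and the integrin call was lost at a median of 0.042.

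**Figure D4:**
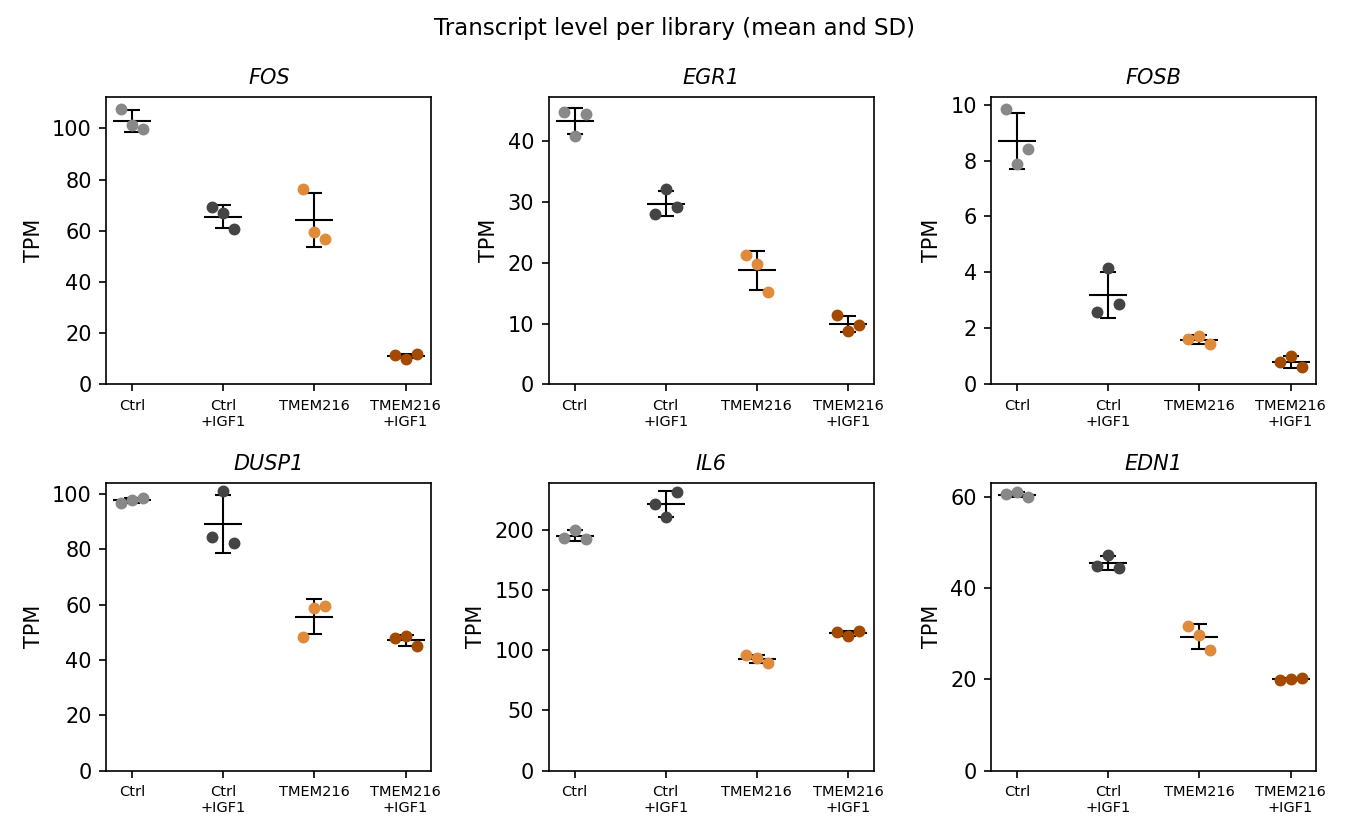
Level in TPM (vertical axes) of FOS, EGR1, FOSB, DUSP1, IL6 and EDN1 in the 4 groups (horizontal axes); points are libraries, and bars show the mean and SD of 3 libraries. FOS lies at 10.0 to 11.7 TPM in TMEM216+IGF1 and at 56.7 TPM or above in the other groups.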

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

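The tests without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1, of scaling, of the ribosomal median without a single library, and all tests of the FOS interaction were set for these patterns after the values they measure, or values close to them, had been seen. The scalings and leave-one-out fits that some of these tests use had been fixed beforehand. The length and GC corrections and the counts of other splits were set before their results were seen, though after the patterns.

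The interaction test, which compares the IGF1 effects in the 2 cell populations, passed for FOS (-1.79 on the log2 scale) and for ENSG00000273049 (fitted value 1.89, no fold being given), which was listed at 0 in every library outside Ctrl. In addition 14 lists passed the interaction test, with median interactions of 0.237 for IGF signalling components, 0.205 for fatty acid synthesis, 0.215 for endoplasmic reticulum stress, 0.169 for NF-kB and cytokines, 0.200 for interferon response, 0.170 for matrix proteases, 0.198 for collagens and matrix, 0.233 for integrins, 0.199 for lysosome and autophagy and 0.257 for fibroblast markers. The lists with negative tests were ribosomal proteins (-0.232), nuclear oxidative phosphorylation (-0.166), histones (-0.111) and ribosome biogenesis, whose median of 0.00904 had the opposite sign to its test and was negative under both other scalings. The median over all features was 0.107, and only the histone call held with an estimated correlation (adjusted p = 0.0260, against 0.492 to 0.724 for the others). The histone median, over members with a length, turned to 0.074 after correction for length and GC content. Without Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 the calls for integrins, lysosome, fatty acid synthesis, endoplasmic reticulum stress, matrix proteases and collagens were lost, at medians of 0.042, 0.072, 0.10, 0.065, 0.055 and 0.087. Single libraries ended the calls for collagens (Ctrl replicates 1 and 2, Ctrl+IGF1 replicate 3, TMEM216 replicates 2 and 3 and TMEM216+IGF1 replicates 1 and 3), interferon response (Ctrl replicate 3, Ctrl+IGF1 replicate 1, TMEM216 replicates 2 and 3 and TMEM216+IGF1 replicates 1 and 3) and fibroblast markers (Ctrl+IGF1 replicate 2, TMEM216 replicate 3 and TMEM216+IGF1 replicate 2). They also ended those for NF-kB and cytokines (Ctrl+IGF1 replicate 2, TMEM216 replicate 3 and TMEM216+IGF1 replicate 3), matrix proteases (TMEM216 replicate 1 and TMEM216+IGF1 replicate 3) and IGF signalling (Ctrl+IGF1 replicate 2). Processing settings ended those for NF-kB and cytokines (median-of-ratios scaling), collagens (no filter or a minimum TPM of 5) and fibroblast markers (no filter).

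The first pattern weighed is the lower ATF4 list in TMEM216 cells. In the comparison without IGF1 the list median was still -0.46 after removal of Ctrl+IGF1 replicate 3 and TMEM216 replicate 1, of which only the latter enters it. With IGF1 the median lay between -0.45 and -0.35 over 20 alternatives, that removal included. After correction for length and GC content it was -0.59 without IGF1 and -0.40 with IGF1. Relative to all genes it stayed at -0.40 or lower under both scalings in both IGF1 conditions. These values argue against these technical accounts as the whole cause of the pattern. An effect of raised TMEM216 is a candidate explanation. So is any other difference between the 2 cell populations or their culture, such as nutrient state, which no test here could decide because each cell population appears once in the design.

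The second pattern is the higher ribosomal and respiratory chain lists in Ctrl+IGF1. Without Ctrl+IGF1 replicate 3 the ribosomal median fell from 0.18 to 0.047, although camera with its preset correlation still called the list. Genes outside both lists changed with transcript length too (rank correlation -0.36), and correction for length and GC content brought the ribosomal median to 0.071 and the respiratory chain median from 0.14 to 0.021. A length-dependent difference between libraries may account for part of this pattern, although deviations from the Ctrl+IGF1 mean followed length in opposite directions in replicates 2 and 3 (rank correlations 0.45 and -0.49) and do not by themselves show a shift against Ctrl. An IGF1 effect on these genes stays open and was not separated from it.

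The third pattern is the FOS interaction. The other 33 members of the immediate early and ERK feedback list had a median interaction of 0.15 with an interquartile half-range of 0.13. That argues against a change shared by the whole list, whose median lay near that of all features (0.107). It does not exclude a change shared with a few members. Of the 33, 9 had a negative interaction, among them EGR1 at -0.31 (SE 0.18), which did not pass, while FOSB stood at 0.69 (SE 0.23). No gene of GENCODE v29 overlaps FOS, which argues against reads moved to an overlapping gene of that annotation. The MSTRG feature that gained most rose by 7.49 TPM against 53.2 TPM lost by FOS. This cannot exclude reads moved to a longer feature, because TPM also depends on feature length. Other annotated features were not checked. With any single library left out the interaction stayed at -1.66 or lower, so it does not rest on 1 library. A difference in the response of FOS to IGF1 between the populations may remain, whether or not it is particular to FOS. It is a hypothesis found and tested on the same data, and the count of splits that follows cannot decide it.

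Other splits of the libraries were counted for each comparison. For the 3 against 3 comparisons 10 splits are too few for a share under 0.05. IGF1 in Ctrl gave 4 genes against at most 2 in another split (1 of 10 splits reached 4). TMEM216 without IGF1 gave 143 against at most 2 (1 of 10). IGF1 in TMEM216 cells gave 2 against at most 4 (2 of 10). TMEM216 with IGF1 gave 211 against at most 1 (1 of 10). For the interaction, 8 of 100 splits gave 2 or more genes, up to 7, a share not under 0.05. These splits redrew IGF1 labels within each cell population, so an IGF1 effect common to both populations enters them. Exchanging the labels in 1 population alone turns the interaction into a multiple of the averaged IGF1 effect, which gave 7 genes. The count is therefore no measure of chance for the interaction and cannot decide it, so chance is not excluded. For the averaged TMEM216 effect 1 of 100 splits, the real grouping itself, reached 682 genes (highest other 3). For the averaged IGF1 effect 1 of 100, again the real grouping, reached 7 (highest other 3). Both shares lie under 0.05, which argues against a chance split of these libraries. Both contrasts were chosen after seeing the data, and the splits cannot tell whether the replicates are separate cultures.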

How the results depend on the processing

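Removal of Ctrl+IGF1 replicate 3 and TMEM216 replicate 1 (called the 2 libraries apart below), averaged contrasts, the length and GC correction, camera without the trend and the p53 list without shared genes were tests chosen after seeing the data. TMEM216 itself kept its direction and its call under every alternative run, at log2 2.81 to 3.12. Named genes that passed were never reversed: of 2056 recomputed values 1624 kept the call and 432 lost it. Of 5195 recomputed values of named genes that had not passed, 5096 stayed so, 71 passed and 28 changed sign. The cause of each change below was not tested, except that a minimum fold can only remove genes. Fits of fewer libraries called fewer genes in some cases and more in others. The scalings moved the median of all features by at most -0.0958 (interaction). TPM gives no depth, so the limit set by depth is unknown.

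For IGF1 in Ctrl (4 genes), the count was 0 with a pseudocount of 0.1 or a TPM of at least 5, 1 with no filter or only the 6 libraries compared, 2 with quantile normalization or a log2 fold change of at least 1, and 1 to 5 leaving out single libraries. For TMEM216 without IGF1 (143), it was 288 without the 2 libraries apart, 49 with only the 6 libraries, 17 with the fold minimum and 43 to 273 leaving out single libraries. For IGF1 in TMEM216 cells (2), it was 7 with the pseudocount of 0.1, 4 with a TPM of at least 5, 1 with no filter, median-of-ratios scaling or without the 2 libraries apart, and 1 to 6 leaving out single libraries. For TMEM216 with IGF1 (211), it was 49 with only the 6 libraries, 27 with the fold minimum and 84 to 462 leaving out single libraries. For the interaction (2), it was 1 with the pseudocount of 0.1, a TPM of at least 5, quantile normalization, median-of-ratios scaling or without the 2 libraries apart, and 1 to 3 leaving out single libraries. Averaged over the other factor, the IGF1 count (7) was 4 without the 2 libraries apart, 1 with the fold minimum and 1 to 11 leaving out single libraries, and the TMEM216 count (682) was 1061, 22 and 392 to 906.

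Across all groups, replicate numbers did not clearly pair the libraries. Same-numbered libraries had correlations of deviations from -0.286 to 0.165, 4 of 18 above 0.1, and 4 of 12 libraries correlated best with their own number. All 4 values above 0.1 joined groups with the same IGF1 condition. Ctrl and TMEM216 replicates 1, 2 and 3 had values of 0.114, -0.0024 and 0.107. Ctrl+IGF1 and TMEM216+IGF1 replicates 1, 2 and 3 had values of 0.011, 0.165 and 0.125. Weak pairing within an IGF1 condition was not excluded, and no block within it was fitted. With the replicate block the counts were 1 (IGF1 in Ctrl), 77 (TMEM216 without IGF1), 1 (IGF1 in TMEM216), 140 (TMEM216 with IGF1), 1 (interaction) and 1 (averaged IGF1).

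List counts with an estimated correlation were 1 in each of the 5 contrasts, from 12, 18, 14, 18 and 14. With fry they were 0 for IGF1 in Ctrl, 8 for TMEM216 without IGF1, 1 for IGF1 in TMEM216, 9 for TMEM216 with IGF1 and 0 for the interaction. Camera without the trend gave 12, 16, 14, 18 and 14.

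The changes of sign were all in genes near 0. Without the 2 libraries apart, TMEM216 stood at -0.013 for IGF1 in Ctrl, -0.062 for IGF1 in TMEM216 and -0.048 for the interaction; IGF1R at 0.046 for TMEM216 without IGF1; IRS1 at -0.016 for IGF1 in TMEM216 and -0.091 for TMEM216 with IGF1; and IRS2 at -0.12 for the interaction. With quantile normalization, IGF1R stood at 0.040 for TMEM216 without IGF1, IRS1 at -0.019 for TMEM216 with IGF1, and TMEM216 and IRS2 at -0.035 and -0.089 for the interaction. With median-of-ratios scaling, IRS1 stood at -0.014 for TMEM216 with IGF1, and TMEM216 and IRS2 at -0.035 and -0.041 for the interaction. Leaving out single libraries, TMEM216 ranged from -0.013 to 0.14 (IGF1 in Ctrl), -0.062 to 0.24 (IGF1 in TMEM216) and -0.11 to 0.19 (interaction); IGF1R from -0.11 to 0.046 (TMEM216 without IGF1); IRS1 from -0.016 to 0.19 (IGF1 in TMEM216) and -0.091 to 0.16 (TMEM216 with IGF1); and IRS2 from -0.17 to 0.025 (TMEM216 with IGF1) and -0.040 to 0.16 (interaction).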

Other observations

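Averaged over both cell populations, a contrast added after seeing the data, IGF1 went with lower levels of 7 features and higher levels of none (768 features had an unadjusted p under 0.05 in limma). Named after their values were seen, they were the early response genes FOS (log2 -1.54), FOSB (-0.88) and EGR1 (-0.69), EDN1 (-0.46), the metastasis suppressor KISS1 (-0.76), ASNS (-0.35) and ENSG00000273049. Averaged over IGF1, TMEM216 cells differed in 682 features, 262 higher and 420 lower. Over the 681 of these other than TMEM216, the effects without and with IGF1 correlated with an r of 0.860, a value raised by choosing genes on both effects. The IGF1 count of 7 was 1 without Ctrl replicate 2 or 3, 2 without Ctrl+IGF1 replicate 1, TMEM216 replicate 1 or 2 or TMEM216+IGF1 replicate 1, 3 without TMEM216+IGF1 replicate 2 or 3, 4 without TMEM216 replicate 3 and 11 without Ctrl+IGF1 replicate 3. The TMEM216 count of 682 was 418, 392 and 408 without Ctrl replicates 1, 2 and 3, 423 without Ctrl+IGF1 replicate 1, 424 without TMEM216 replicate 2, and 408 and 420 without TMEM216+IGF1 replicates 1 and 2.

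None of the genes near TMEM216 in the annotation listed here rose in TMEM216 cells without IGF1: TMEM138 was at log2 0.0037, CYB561A3 at -0.56, TKFC at -0.31, DDB1 at -0.22, CPSF7 at -0.14 and SDHAF2 at -0.014, none past the threshold. Markers of other cell types were few: 6 of 20 leukocyte, 4 of 15 endothelial, 6 of 15 fibroblast and 0 of 10 erythroid genes passed the filter. The highest were LAPTM5 among leukocyte genes (255 TPM over all libraries), ESAM among endothelial genes (153 TPM) and COL1A1 among fibroblast genes (49.9 TPM). The leukocyte, luminal mammary, mesenchymal, EGF receptor, Notch, TGF-beta and heat shock lists did not pass in any contrast, and the endothelial and erythroid lists had too few members to test.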
